A study of Mus musculus with 6 samples.

How the data were processed

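The series holds 6 single-channel Affymetrix arrays of mouse mammary stem cells cultured as organoids, 3 wild type and 3 Mll3-null. Per the labels' protocols, total RNA was isolated with a commercial kit and biotinylated cRNA was prepared from it. Per the submitters' processing notes, the arrays were processed with Affymetrix Expression Console. Its version, the summarization and normalization methods and the genome build are not given in the sources used here. The deposited values were taken as log2 expression, 1 value per probe set and array, because they run from 1.72 to 13.56 with nearly equal quartiles on all arrays (lower quartile 3.27 to 3.29, upper quartile 6.51 to 6.59). Near-equal quartiles mean that the arrays were put on a common scale before deposit, so a change in total RNA per cell cannot be seen, and no detection values were used, so dim genes were not removed. The 6 columns were matched to samples by their names, and 0 other columns of sample values were present.

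Probe sets were named from the platform annotation table. Of 41345 probe sets, 25335 were listed with a gene, 23521 with exactly 1 symbol and 1814 with several. The 16010 unlisted probe sets are unnamed here, and probe sets with several symbols were not used for named genes. For the 1082 genes with more than 1 probe set, the one with the highest mean over the 6 arrays stood for the gene, which left 22180 genes. Gene lists were written from general knowledge before the data were examined, as were the design, the alternatives and the rule for named genes. The 32 lists hold 656 distinct genes, of which 605 had a value, 2 of them through an older symbol. The others, such as Krt5, were not paired with a probe set of their own and are not reported here. Chromosomes were taken through gene identifiers from the GRCm38.p6 annotation for 99.2% of the genes, only to group neighbouring genes, and no coordinates are printed.

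Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, genotype as the only term, all 6 arrays), with Benjamini-Hochberg adjustment over the 22180 genes and a threshold of 0.05. Differences are Mll3-null minus WT on the log2 scale, with the moderated standard error. Gene lists were tested with camera at a preset inter-gene correlation of 0.01 and adjusted over the 32 lists, with camera at an estimated correlation and fry beside it. The mean of a list on each array was also compared by an exact two-sided permutation test, whose smallest p with 3 against 3 arrays is 0.1. Counts adjusted over the list alone use Benjamini-Hochberg within that list. For the chromosome medians, genes with a mean log2 value over 6 were called expressed and those under 4 dim, both limits set after the data were seen.

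The rule for named genes was the targeted gene, the 12 genes of largest change in each direction among those past the threshold with non-overlapping groups, and up to 4 members of each list past it. Predicted genes, small RNAs, receptor families, histones and pseudogenes were left out. Because fewer than 5 genes passed in either direction, the rule's fallback applied: the 12 genes with the smallest p in each direction and the 2 list members with the smallest p. Genes named for another reason are marked as such.

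The replicate numbers 1 to 3 occur in both groups, but no label ties them to a shared animal, line or day, and the fit used no block. The scripts were tested on simulated data: in 10 simulated comparisons of all 22180 genes with a known set of changed genes each, limma recovered 68.2% of 2-fold, 91.5% of 4-fold and 97.6% of 8-fold changes, with 82 false calls in all. A simulated shift of 0.33 in the HIF target list was called in 10 of 10 runs, with 3 calls of other lists. Which lists these were was not recorded, and the glycolysis and HIF pathway lists share members with the shifted list. That simulation drew the genes independently, so it says nothing of calls among correlated genes. Alternatives covered the spread model, array weights, filters on dim genes, quantile normalization, median centring, the choice of probe set, all probe sets, the replicate block, a stricter threshold and leaving out each array. A further 2 were chosen after seeing the data: leaving out the genes of chromosomes 1 and 10, and leaving out WT replicate 1 and Mll3-null replicate 3 together.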

Results

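Gene expression was measured in mouse mammary stem cells grown as organoids, 3-dimensional cultures of mammary epithelial cells. The study asked what deletion of MLL3 does to these cells. MLL3, encoded by Kmt2c, is a histone methyltransferase that places monomethyl marks on histone H3 lysine 4 at enhancers, and the cell lines were made by CRISPR. The 6 arrays fall into 3 from wild-type (WT) cells and 3 from Mll3-null cells, each labelled a biological replicate. The labels do not say whether the replicates of a group came from separate cell lines or from separate cultures of a line, so the p-values measure the spread between these samples only. The deposited values are log2 expression summaries for 41345 probe sets, of which 22180 genes could be named and tested. The array medians lay between 4.35 and 4.40, and the number of arrays limits the precision.

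The arrays did not separate cleanly by genotype. Mll3-null replicate 3 stood apart: 123 genes lay more than 1 log2 unit above, and 294 more than 1 unit below, all 5 other arrays, against 9 to 33 above and 1 to 24 below for each of the other arrays. Its basal keratins were far lower than elsewhere, with Krt14 at 6.65 against a mean of 12.23 on the other 5 arrays and Krt17 at 4.80 against 10.21 (genes named after their values were seen). Mll3-null replicate 1 correlated most highly with WT replicate 1 (Pearson r = 0.990 across probe sets, which are not independent replicates). Grouped by the chromosome given in the GRCm38.p6 gene annotation, the 510 expressed genes of chromosome 1 had a median 0.30 log2 units above the 6-array median in Mll3-null replicate 3 and 0.09 above it in Mll3-null replicate 2, against -0.06 in Mll3-null replicate 1. The 443 expressed genes of chromosome 10 lay 0.22 above it in WT replicate 1 and between -0.05 and 0.01 on the other 5 arrays.

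**Figure D1:**
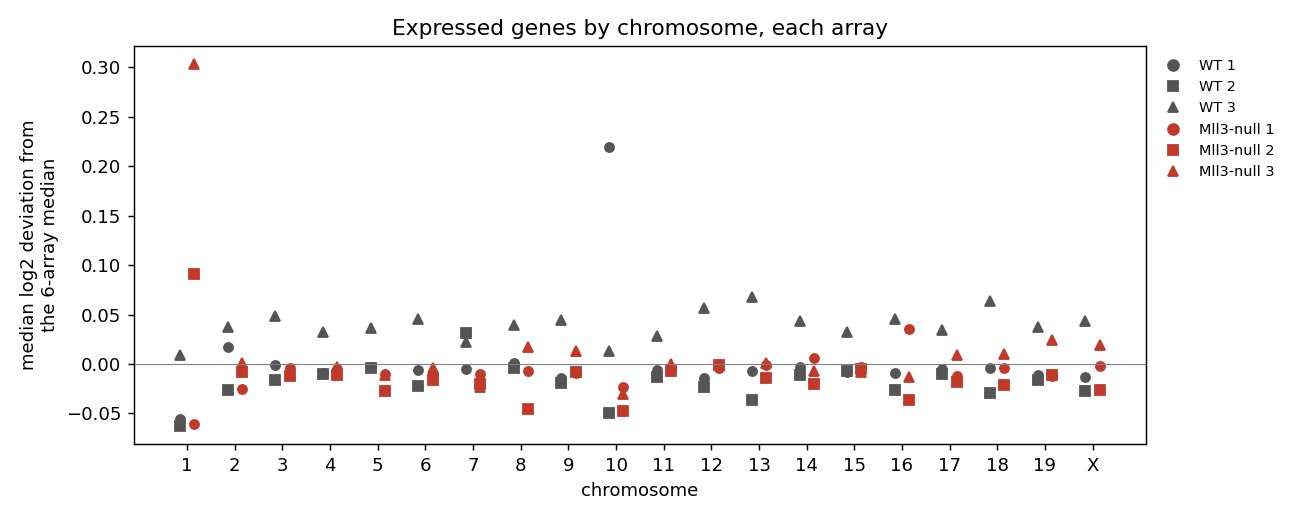
Median log2 deviation (y axis) of the expressed genes of each chromosome (x axis) from each gene's 6-array median, one point per array, grey for WT and red for Mll3-null, with the marker shape giving the replicate. Chromosome 1 stands at 0.30 in Mll3-null replicate 3 and chromosome 10 at 0.22 in WT replicate 1, above every other chromosome of those arrays.

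The targeted gene was examined first. Kmt2c, read by 1 probe set, was at 6.01 ± 0.55 in WT and 6.11 ± 0.29 in Mll3-null cells (log2, mean ± SD, n = 3 each). The difference of 0.10 ± 0.29 (SE) had a 95% interval from -0.60 to 0.80 and an adjusted p of 0.95 (limma, Benjamini-Hochberg). The direction changed without WT replicate 2 (-0.11) or without Mll3-null replicate 2 (-0.06). The mRNA level did not separate the groups. Where the probe set lies against the altered part of the gene is not given in the sources used here, so this level does not test the genotype labels. Of the 16 measured members of the MLL and COMPASS complexes, histone methyltransferase assemblies that include the partners of MLL3, none passed the test. The demethylase Kdm6a differed by 0.20 ± 0.10 and the core subunit Dpy30 by -0.21 ± 0.10 (log2, SE), and the list did not shift as a whole (median -0.05, camera adjusted p = 0.50).

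No single gene differed between Mll3-null and WT cells once all 22180 genes were corrected for. With limma's moderated test 0 genes had an adjusted p under 0.05, in either direction, and the smallest adjusted p was 0.84. At an unadjusted p under 0.05 there were 1093 genes, 557 higher and 536 lower in Mll3-null cells, where 1109 are expected by chance. That unadjusted count was 2742 without Mll3-null replicate 1 and 716 without Mll3-null replicate 2, with 0 genes past the corrected threshold in both cases. The groups did not overlap for 10.7% of genes, where chance gives 10%. By group means 118 genes were at least 2-fold higher and 138 at least 2-fold lower, and 58 of these 256 had non-overlapping groups. On simulated data with the spread of these arrays and a planted set of 2-fold to 8-fold changes, the same test recovered 68.2% of 2-fold and 91.5% of 4-fold changes. Many planted changes ease the Benjamini-Hochberg threshold, so these shares do not tell how many real changes could be missed here.

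The 12 genes with the smallest p among those higher in Mll3-null cells are described by their values, none having passed the correction. They held 3 genes of the response to low oxygen: Vegfa, the angiogenic growth factor, at 8.32 ± 0.28 in WT and 9.52 ± 0.16 in Mll3-null cells (log2, SD, n = 3 each), Ndrg1, a stress-responsive gene, at 7.60 ± 0.36 and 8.87 ± 0.15, and Ero1a, an oxidase of protein folding in the endoplasmic reticulum, at 10.10 ± 0.20 and 10.94 ± 0.18. They correspond to fold differences of 2.31, 2.42 and 1.79. Chac1, a glutathione-degrading enzyme, at 3.12-fold, and Asns, asparagine synthetase, at 2.71-fold, are in the stress response list. The others were Pck2, the mitochondrial phosphoenolpyruvate carboxykinase, at 2.45-fold, the interferon-inducible GTPase Iigp1 at 2.61-fold, the homeobox gene Dlx5 at 1.68-fold, the hedgehog co-receptor Boc at 1.47-fold, Nat8f3 at 1.42-fold, the zinc finger gene Sall1 at 1.37-fold and the receptor gene Gpr35 at 1.33-fold. Their unadjusted p ran from 2.1e-04 for Vegfa to 0.0036 for Nat8f3, and the Mll3-null arrays lay above all WT arrays for each of the 12. Of these, Sall1 (3.02 in WT and 3.48 in Mll3-null cells), Dlx5 (3.97 and 4.72) and Gpr35 (4.17 and 4.58) lay under or little above 4, the limit for dim genes.

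Among the 12 genes with the smallest p on the lower side, again none past the correction, Plekhs1 had the widest difference, 9.18 ± 0.55 in WT against 7.32 ± 0.57 in Mll3-null cells, or 3.64-fold lower. Grem1, a secreted BMP antagonist, was 2.60-fold lower and Ccn1, a matricellular protein, 2.07-fold lower. Aen, a nuclease induced by p53, was 1.71-fold lower, and Tnfrsf10b, a death receptor also induced by p53, 1.57-fold lower. The cell cycle inhibitor Cdkn2b was 1.68-fold lower, Gimap9 1.66-fold, the polyamine-catabolic enzyme Sat1 1.61-fold, the semaphorin receptor Plxna2 1.60-fold, Sac3d1 1.43-fold, extracellular superoxide dismutase Sod3 1.36-fold and Lxn 1.32-fold. Unadjusted p ran from 7.8e-04 for Sat1 to 0.0020 for Grem1.

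**Figure D2:**
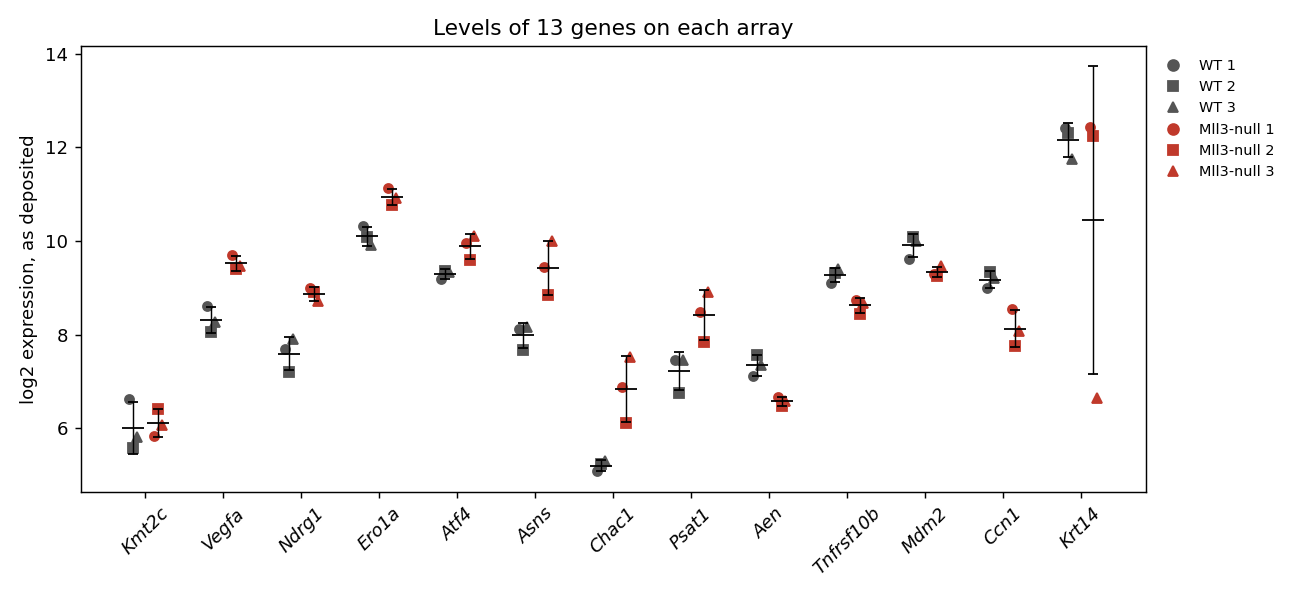
Deposited log2 expression (y axis) of the targeted gene, 11 genes of the hypoxia, stress, p53 and YAP lists and Krt14 (x axis); points are arrays, grey for WT and red for Mll3-null, and bars are the mean ± SD of 3 arrays. Vegfa lies at 8.32 ± 0.28 in WT and 9.52 ± 0.16 in Mll3-null cells without overlap, Kmt2c overlaps, and Krt14 is at 6.65 in Mll3-null replicate 3 alone.

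The list of HIF targets, genes switched on by the hypoxia-inducible factors, was higher in Mll3-null cells. Of its 39 measured members 32 had a higher mean and 7 a lower one, with a median log2 difference of 0.33, and 3 rose when adjusted over the list alone (Vegfa, Ndrg1 and Ero1a), against 0 over all genes. Examples that did not pass either correction are Car9, carbonic anhydrase 9, at 7.36 ± 0.48 in WT and 8.85 ± 0.75 in Mll3-null cells, and Bnip3, a mitophagy receptor, at 5.84 ± 0.16 and 6.64 ± 0.60 (both named after their values were seen). Among the 7 members with a lower mean, Angptl4 differed most, by -1.01 ± 0.77 (log2, SE, also named after its values were seen). The mean of the list's members lay at -0.20 ± 0.16 in WT and 0.20 ± 0.10 in Mll3-null arrays (log2 deviation from the 6-array mean, SD, n = 3 each), with all Mll3-null arrays above all WT arrays. Camera with a preset correlation of 0.01 gave an adjusted p of 7.3e-09 over the 32 lists, while the correlation estimated for this list was 0.12. With an estimated correlation the p was 0.034 before and the adjusted p = 0.45 after correction over the lists, and fry, which asks whether the genes move one way on balance, gave 0.022 and an adjusted p of 0.44. The exact permutation test of the array means gave p = 0.1, the smallest that 3 against 3 allows. HIF signalling is a known theme of this study, so the choice of this list is not independent evidence of its direction.

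The list of glycolytic enzymes and transporters shares 6 of its 17 measured members with the HIF target list and is not independent of it. It was higher, with 15 members at a higher mean (median 0.22, camera adjusted p = 2.2e-04; adjusted p = 0.45 with an estimated correlation). Its array means overlapped between the groups (-0.41 to 0.14 in WT, 0.06 to 0.25 in Mll3-null arrays; exact permutation p = 0.2). Pfkp, a phosphofructokinase, stood 0.93 ± 0.22 and Pgk1, phosphoglycerate kinase, 0.48 ± 0.15 log2 units higher (SE), neither past a correction over the list alone or over all genes. The 11 members not shared had a median of 0.14, with 10 at a higher mean, and were not tested apart. Without Mll3-null replicate 1 the list's adjusted p was 0.051. Of 13 components of the HIF pathway itself, 2 of them (Egln1 and Egln3) also in the HIF target list, 11 had a higher mean (median 0.08, camera adjusted p = 0.023; adjusted p = 0.45 with an estimated correlation). The prolyl hydroxylase Egln3, itself a HIF target, differed by 2.39 ± 0.84 and Epas1, which encodes HIF-2 alpha, by 0.34 ± 0.21, neither past the correction. Without WT replicate 2 the difference of Egln3 was 1.53, and without Mll3-null replicate 3 that of Epas1 was 0.16. That call was lost without any one of WT replicate 2 (adjusted p = 0.11), WT replicate 3 (0.051), Mll3-null replicate 2 (0.054) or Mll3-null replicate 3 (0.054). Of the 27 oxidative phosphorylation genes 13 had a higher and 14 a lower mean, with no shift of the list (camera adjusted p = 0.56). Atp5d differed by -0.32 ± 0.10 and Ndufb8 by -0.23 ± 0.08, not past the correction.

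The integrated stress response and unfolded protein response list was higher in Mll3-null cells, with 19 of 23 measured members at a higher mean, a median of 0.54 and a camera adjusted p of 7.8e-08. The adjusted p = 0.45 with an estimated correlation and 0.44 by fry. When adjusted over the list alone 4 members rose, against 0 over all genes: Chac1 by 1.64 ± 0.33, Asns by 1.44 ± 0.30, Psat1, a serine synthesis enzyme, by 1.19 ± 0.31, and Atf4, the transcription factor of this response, by 0.59 ± 0.15 (log2, SE; Psat1 and Atf4 named after their values were seen). The array means were -0.32 ± 0.11 in WT and 0.32 ± 0.39 in Mll3-null arrays without overlap (exact permutation p = 0.1, the smallest possible), the highest being 0.70 in Mll3-null replicate 3.

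Targets of p53 were lower in Mll3-null cells. Of 18 measured members 14 had a lower mean (median -0.35, camera adjusted p = 1.8e-06; adjusted p = 0.45 with an estimated correlation and 0.44 by fry), and 3 fell when adjusted over the list alone, against 0 over all genes: Aen by -0.77 ± 0.13, Tnfrsf10b by -0.65 ± 0.12 and Mdm2, the ubiquitin ligase that restrains p53, by -0.57 ± 0.14 (log2, SE; Mdm2 named after its values were seen). The array means were 0.16 ± 0.17 in WT and -0.16 ± 0.05 in Mll3-null arrays without overlap (exact permutation p = 0.1, the smallest possible). Targets of YAP and TAZ, the co-activators of the Hippo pathway, were lower in 16 of 17 members (median -0.36, camera adjusted p = 5.2e-05; adjusted p = 0.45 with an estimated correlation). Of these, Ccn1 fell by 1.05 ± 0.21 when adjusted over the list alone, and Ankrd1 differed by -1.01 ± 0.42 (-0.64 without WT replicate 2) without passing it. The YAP list mean was lowest in Mll3-null replicate 3, at -0.77 against -0.12 and 0.17 in the other Mll3-null arrays. The WT arrays ran from 0.18 to 0.28, barely apart from these (exact permutation p = 0.1). Besides the p53 and YAP lists, the HIF target, HIF component, stress and stem cell lists reached this smallest p among the 32 lists. By chance 10% of lists would reach it.

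NF-kB and inflammatory genes were lower in 21 of 24 members (median -0.54, camera adjusted p = 1.5e-06; adjusted p = 0.45 with an estimated correlation). Csf2, the cytokine GM-CSF, was at 5.15 ± 0.48 in WT and 4.15 ± 0.35 in Mll3-null cells (SD) and Tnf at 8.94 ± 0.28 and 8.19 ± 0.48, neither past a correction, and the list's array mean was 0.38 in Mll3-null replicate 1, inside the WT range of 0.15 to 0.50, against -0.65 and -0.66 in replicates 2 and 3. Basement membrane and extracellular matrix genes were lower in 21 of 27 members (median -0.44, camera adjusted p = 0.0074; adjusted p = 0.45 with an estimated correlation; 0.18 without Mll3-null replicate 2), among them Timp3, a metalloproteinase inhibitor, at -0.93 ± 0.35 and thrombospondin Thbs1 at -0.58 ± 0.25, neither past a correction and at -0.55 and -0.29 without Mll3-null replicate 3. The array mean of the matrix list was 0.33 in Mll3-null replicate 1, level with the highest WT array, against -0.43 and -0.59 in replicates 2 and 3. Cell cycle genes were lower in 29 of 30 members (median -0.37, camera adjusted p = 4.9e-05; adjusted p = 0.62 with an estimated correlation of 0.81 between the genes). Ccne1 differed by -0.35 ± 0.14 and E2f1 by -0.31 ± 0.16, neither past a correction. E2f1 was at 5.77 in Mll3-null replicate 2 against 6.39 and 6.15 in replicates 1 and 3. The call for the cell cycle list was lost without Mll3-null replicate 3 (adjusted p = 0.28) and without WT replicate 1 (0.050), and the list's array mean was 0.52 in both Mll3-null replicate 1 and WT replicate 1 against -0.79 in Mll3-null replicate 3.

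Interferon-stimulated genes were higher in 25 of 25 members (median 0.27, camera adjusted p = 1.2e-04; adjusted p = 0.62 with an estimated correlation of 0.57; 0.057 without Mll3-null replicate 2). The transcription factor gene Irf9 differed by 0.37 ± 0.13 and the antiviral GTPase Mx2 by 0.92 ± 0.36 (0.51 without Mll3-null replicate 2), neither past a correction. The array means of the list overlapped, at 0.17, 0.56 and -0.24 in Mll3-null replicates 1 to 3 against -0.36 to 0.20 in WT (exact permutation p = 0.3). Milk protein and alveolar differentiation genes were higher in 14 of 16 members (median 0.37, camera adjusted p = 0.0011; adjusted p = 0.45 with an estimated correlation). The casein gene Csn1s1 differed by 1.49 ± 0.71 and Stat5b, a transcription factor of the prolactin pathway, by 0.39 ± 0.18, neither past a correction, and without WT replicate 2 they differed by 0.76 and 0.26. The list's array mean was -0.28 in Mll3-null replicate 1, inside the WT range of -0.54 to -0.06, against 0.53 and 0.49 in replicates 2 and 3.

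**Figure D3:**
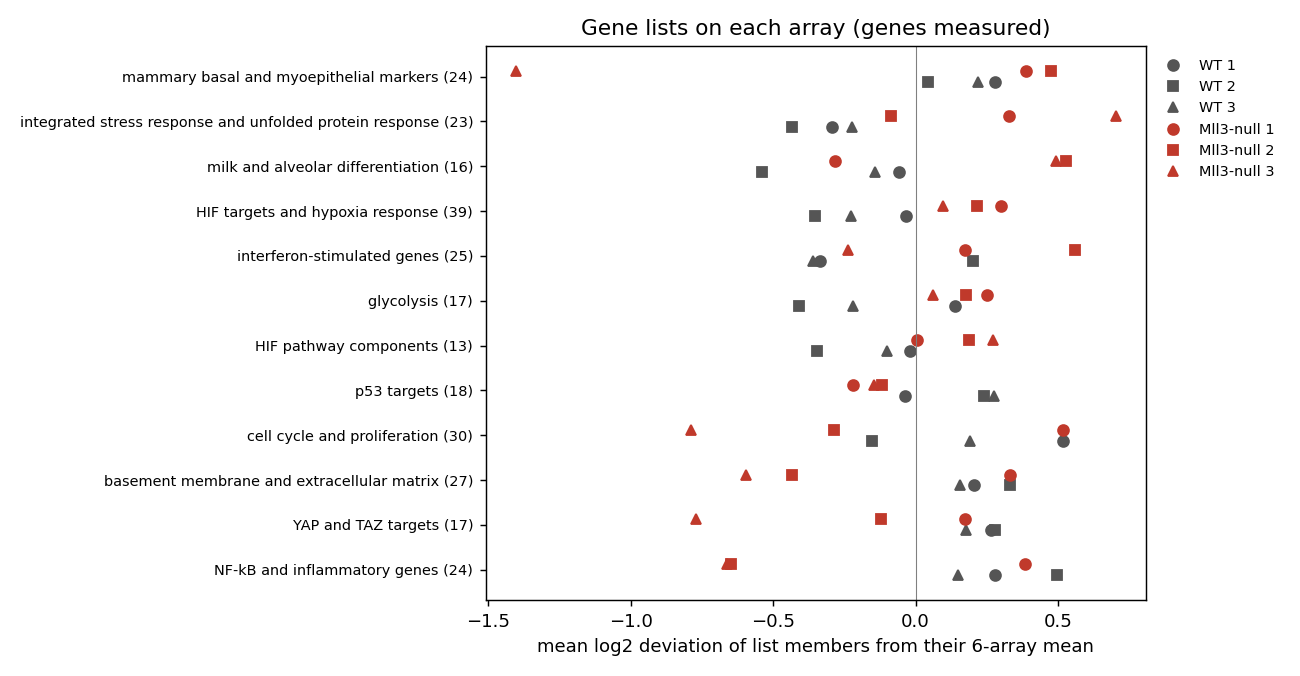
Mean log2 deviation (x axis) of the measured members of each list from their 6-array mean, for the 11 lists called with a preset correlation and, at the top, the basal marker list (y axis, number of genes in brackets); points are arrays, grey for WT and red for Mll3-null. The HIF target list has all Mll3-null arrays above all WT arrays (0.20 ± 0.10 against -0.20 ± 0.16), and the basal list is at -1.40 in Mll3-null replicate 3 alone.

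The lists of basal, stem cell, luminal progenitor, hormone-sensing and general luminal markers of the mammary epithelium were not called. The basal and myoepithelial list went both ways by array (16 of 24 members with a lower mean, median -0.32, camera adjusted p = 0.28), and its array means were 0.39 and 0.47 in Mll3-null replicates 1 and 2 and -1.40 in replicate 3, against 0.04 to 0.28 in WT. Without Mll3-null replicate 3 the list was called higher (adjusted p = 0.022), and without replicate 2 it was called lower (0.038). Igfbp5, an IGF-binding protein, differed by 2.81 ± 1.03 and the integrin Itga6 by 0.28 ± 0.11. Of the 18 stem cell markers 11 had a lower mean (median -0.26, camera adjusted p = 0.11). With the replicate block the stem cell list was called lower (camera adjusted p = 0.023). The array means of this list were 0.09, -0.05 and -0.49 in Mll3-null replicates 1 to 3, all below the WT range of 0.11 to 0.18 (exact permutation p = 0.1, the smallest possible). Inhba differed by -1.39 ± 0.61 and Lgr6 by -1.12 ± 0.49. Luminal progenitor markers (17 measured, median 0.05, adjusted p = 0.69), with Ltf, lactoferrin, at -1.64 ± 0.61 and Itga2 at -1.09 ± 0.45, did not shift detectably. Neither did hormone-sensing luminal markers (14 measured, median -0.19, adjusted p = 0.50), with Wnt4 at -0.65 ± 0.21 and the estrogen receptor gene Esr1 at -0.42 ± 0.23. Esr1, on chromosome 10, was at 7.01 in WT replicate 1 against 6.25 and 6.47 in WT replicates 2 and 3. General luminal markers (19 measured, median 0.02, mean -0.02, adjusted p = 0.70) went both ways, with Cldn4 at -1.58 ± 0.40 and the mucin gene Muc1 at 2.11 ± 0.64. None of these 10 genes passed the correction. Without Mll3-null replicate 3 the differences were 1.78 for Igfbp5, -0.76 for Inhba, -0.68 for Lgr6 and -1.06 for Ltf.

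Markers of cells that a mammary culture could hold besides epithelium differed little in their list medians. The list medians were -0.05 for fibroblast (adjusted p = 0.30), 0.01 for endothelial (0.94), 0.02 for immune (0.75) and -0.02 for adipocyte markers (0.94). The pair of genes with the smallest p was Col6a1 (-0.86 ± 0.39) and Col6a2 (-0.76 ± 0.38) for fibroblasts, Esam (0.15 ± 0.11) and Sox17 (-0.11 ± 0.11) for endothelium, Coro1a (0.14 ± 0.11) and Fcer1g (0.11 ± 0.13) for immune cells, and Plin1 (0.29 ± 0.14) and Pparg (0.34 ± 0.21) for adipocytes, none past the correction. Col6a1 and Col6a2 lie on chromosome 10, raised in WT replicate 1, where both were highest (9.14 and 7.85). Pparg was at 4.62 in Mll3-null replicate 3 against 3.76 and 4.11 in replicates 1 and 2. The fibroblast list had a mean of -0.22, with -0.42 in Mll3-null replicate 3, and the adipocyte list a mean of 0.02, opposite in sign to its median.

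The other 10 lists were not called by camera with a preset correlation, and none of the genes named here passed the correction. The epithelial-mesenchymal transition list (median -0.27, adjusted p = 0.28) held Mmp9 at -0.47 ± 0.13 and Mmp2 at 0.52 ± 0.20, and was called lower without Mll3-null replicate 1 (0.041). The squamous keratinisation list (median 0.04, mean -0.04, adjusted p = 0.22) held Sprr1a at 1.03 ± 0.29 and Klk7 at 0.28 ± 0.10, and was called higher without Mll3-null replicate 3 (0.0013). The cholesterol and fatty acid synthesis list (median -0.11, adjusted p = 0.50) held Elovl6 at 0.38 ± 0.16 and Srebf1 at 0.80 ± 0.40, and was called lower without Mll3-null replicate 1 (0.021). Srebf1 was at 9.72 in Mll3-null replicate 3 against 7.99 and 8.86 in replicates 1 and 2, and Elovl6 was lowest in WT replicate 2 (9.58). NRF2 targets (median -0.11, mean 0.005, adjusted p = 0.22) held Gclc at -0.62 ± 0.16 and Abcc4 at -0.70 ± 0.24. TGF-beta targets (median -0.13, adjusted p = 0.36) held Bambi at 0.42 ± 0.14 and Id1 at -0.90 ± 0.36. Id1 was at 6.12 in Mll3-null replicate 2 against 7.08 and 7.23 in replicates 1 and 3. PI3K and growth factor signalling genes (median -0.06, adjusted p = 0.30) held Pik3cb at -0.52 ± 0.13 and Irs2 at 0.65 ± 0.23. Irs2 was at 6.50 in Mll3-null replicate 2 against 5.68 and 5.78 in replicates 1 and 3. The Notch list (median 0.00, adjusted p = 0.85) held Dll1 at 1.01 ± 0.54 (0.46 without Mll3-null replicate 3) and Hes1 at 0.25 ± 0.14. Hes1 was also highest in that array, at 9.27 against 8.80 and 9.07 in Mll3-null replicates 1 and 2. The Wnt list (median 0.00, adjusted p = 0.77) held Tcf7l2 at 0.28 ± 0.11. Notch and Wnt means were -0.05 and -0.07, and their test pointed lower. Immediate-early and heat-shock genes (median -0.08, adjusted p = 0.73) held Zfp36 at 0.55 ± 0.22 and Hspb1 at -0.62 ± 0.30, and ribosomal protein genes (median -0.02, adjusted p = 0.28) held Rpl11 at -0.34 ± 0.14 and Rps16 at -0.19 ± 0.10. Hspb1 was at 6.66 in Mll3-null replicate 3 against 7.88 and 7.60 in replicates 1 and 2.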

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

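Leaving out the genes of chromosomes 1 and 10, and leaving out WT replicate 1 with Mll3-null replicate 3, were chosen after the results were seen. No gene passed the adjusted threshold in limma under any alternative run, and the unadjusted counts ran from 542 in the brighter part of the genes, where fewer genes were tested, to 2742 without Mll3-null replicate 1, with 2075 over all probe sets and 2504 with array weights. None of the 80 other named genes passed in any of 1413 comparisons, and Fcer1g alone changed direction, at -0.061 without WT replicate 1 and Mll3-null replicate 3 and -0.0086 to 0.21 with single arrays left out. Kmt2c ran from -0.11 to 0.41 with single arrays left out, and was -0.056 without Mll3-null replicate 2. No label says what a shared replicate number means. Same-number correlations of deviations were 0.03, 0.08 and 0.31, the last being the highest of all pairs, and WT replicate 2 correlated best with Mll3-null replicate 1 (0.22). These values do not settle whether samples of the same number share an origin. A replicate block gave 0 genes, 1290 at an unadjusted p under 0.05, and 12 called lists in place of 11, adding the stem cell markers (0.023). The adipocyte list turned higher with the block (0.93). Adjusted p-values are given in brackets from here on, and the cause of a lost or turned call was not tested.

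With an estimated correlation 0 lists were called: the cell cycle and interferon lists had 0.62 and the other 9 had 0.45. The correlations estimated for the called lists ran from 0.03 for HIF components to 0.81 for cell cycle, all above the preset 0.01. With fry 0 were called, with 0.47 for matrix, 0.79 for cell cycle, 0.73 for interferon and 0.44 for the other 8. Over single arrays left out, HIF components ran from 0.016 to 0.11, matrix from 1.6e-04 to 0.18, cell cycle from 5.9e-14 to 0.28, glycolysis from 4.7e-07 to 0.051 and interferon from 2.7e-12 to 0.057, while the other 6 called lists stayed under 0.05. Lists that were not called and turned direction in at least 1 such comparison ran from 0.022 to 0.60 (basal), 0.13 to 0.88 (luminal progenitor), 0.13 to 0.87 (hormone-sensing), 0.28 to 0.96 (general luminal), 0.041 to 0.91 (epithelial-mesenchymal transition), 0.094 to 0.87 (oxidative phosphorylation), 0.50 to 0.98 (endothelial), 0.46 to 0.93 (immune), 0.54 to 0.92 (adipocyte), 0.50 to 0.99 (Notch), 0.36 to 0.94 (Wnt), 0.021 to 0.94 (cholesterol) and 0.21 to 0.93 (immediate-early). Without WT replicate 1 and Mll3-null replicate 3 the directions turned for the cell cycle (0.43), basal (0.0024, called), COMPASS (0.90), luminal progenitor (0.95), epithelial-mesenchymal transition (0.59), fibroblast (0.99), adipocyte and Wnt (0.31 each), Notch (0.45) and immediate-early lists (0.28), and keratinisation was called (6.8e-04). The endothelial list turned with quantile normalization (0.80), the adipocyte list without the dimmest genes (0.73), and the adipocyte, Notch and Wnt lists with array weights (0.95 each). In all, 15 lists that were not called turned in 36 comparisons, and only the basal list was called in any, in 2 of them. In the brighter part of the genes 29 of the 32 lists kept enough members for a test.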

Other observations

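Tests of background, neighbouring genes and genotype for the chromosome shifts, of poor RNA, non-epithelial cells and genotype for the basal markers, and of replicate 3 alone and culture growth for the HIF targets were chosen after the results were seen. The genes that set Mll3-null replicate 3 apart were named after their values were seen. Among its lowest genes against the other 5 arrays, the keratin Krt6a was at 4.19 against a mean of 10.77, the hemidesmosomal collagen Col17a1 at 5.31 against 9.76, the desmosomal cadherin Dsg3 at 4.98 against 9.42, Trim29 at 5.36 against 10.48, and the matrix proteins Sparc and Postn at 4.56 and 3.37 against 9.54 and 9.32. Its highest genes included the growth factor receptor adaptor Grb10 at 8.77 against 4.28, Scrg1 at 7.92 against 3.60, the acute phase gene Saa2 at 10.36 against 6.29, and Igfbp5 at 12.33 against 8.16. The stress response list was 0.78 log2 units above the other 5 arrays in the median and the cell cycle list at -1.05, with 18 of its 30 members more than 2-fold lower. These are values of 1 array, with no replicate.

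Chromosome 1 in Mll3-null replicate 3 and chromosome 10 in WT replicate 1 had medians 0.30 and 0.22 log2 units above the 6-array medians of their 510 and 443 expressed genes, and the next chromosomes of those arrays 0.02 each. The dim genes of these chromosomes moved by at most 0.00936, which argues against background, though genes this near the floor could hardly show scaling. Scaling of a whole array is argued against by the expressed genes of the other chromosomes. Their medians ran from -0.03 to 0.02 in Mll3-null replicate 3 and from -0.06 to 0.02 in WT replicate 1. The lowest of 10 consecutive blocks of genes on either chromosome was 0.14279, which argues against a few changed neighbours. A part of genotype in the chromosome 1 shift stays open: the median was -0.06092 in Mll3-null replicate 1, inside the WT range of -0.06 to 0.01, but 0.09 in replicate 2, above it. The smaller shift of replicate 2 was likewise positive in all 10 blocks (0.06 to 0.15), with the next chromosome of that array at -9.5e-04. An extra chromosome copy in some or all cells is a candidate explanation for Mll3-null replicate 3 and WT replicate 1. It was not tested for Mll3-null replicate 2, where it stays open as well. The shifts of Mll3-null replicate 3 and WT replicate 1 stayed under 0.58, the log2 ratio of 3 copies to 2. The brighter genes shifted no less than the dimmer ones (smaller difference 0.01011, medians 0.37 and 0.25 on chromosome 1, 0.23 and 0.22 on chromosome 10). The size does not tell some cells from all. It differed between the brighter and dimmer genes on chromosome 1, it was taken from a 6-array median that includes the shifted array, and copy number was not measured.

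The basal markers were lower in Mll3-null replicate 3, by a median of 1.29 log2 units, with 13 of 24 more than 2-fold lower and 3 more than 2-fold higher (Oxtr, Dll1 and Igfbp5). Poor RNA or a poor array is argued against as the whole cause by the median absolute deviation of ribosomal protein and oxidative phosphorylation genes, which was 0.13717, although the other 5 arrays had 0.069 to 0.082 and this array also had the widest interquartile range of deviations over all genes (0.231 against 0.158 to 0.184). Replacement by fibroblasts, endothelium, immune cells or adipocytes is argued against by their highest list median of -0.00461. Genotype alone is argued against by the other Mll3-null arrays, whose lower basal median was 0.06167, above all WT arrays. A culture with fewer basal cells may account for it, but the luminal lists do not decide: their medians were 0.14, 0.25 and 0.0802, with standard errors of 0.35, 0.30 and 0.13.

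The HIF target list was called higher in Mll3-null cells by camera with a preset correlation, and not with an estimated correlation (adjusted p = 0.45) or by fry (0.44). Only 4 of its 39 measured members lie on chromosomes 1 or 10, and the call stayed without the genes of those chromosomes (camera adjusted p = 8.361e-10, median 0.33). This argues against those members as its cause, but the removal cannot show effects of the chromosome shifts on genes elsewhere. Mll3-null replicate 3 as the sole cause is argued against by its list mean of 0.09, the lowest of the Mll3-null arrays (0.30 and 0.22 in replicates 1 and 2). Leaving out that array therefore widens the difference of the means, so the call without it (camera adjusted p = 2.696e-12) adds no support. Over single arrays left out the camera adjusted p ran from 2.7e-12 to 1.6e-04. An effect of genotype stays open, and so does a slower or denser culture of the Mll3-null group, which could also raise hypoxia genes: the cell cycle list differed by -0.36902 between the groups, but Mll3-null replicate 1, with the highest HIF list mean (0.30), was at 0.52, level with the highest WT array. Of the 10 splits of the 6 arrays, 1 gave a camera adjusted p as small for this list, the real one (7.3e-09; smallest other 2.9e-07). Splits other than by genotype also called the list. Among them were WT replicate 1 with Mll3-null replicates 1 and 3 against the rest (1.2e-04) and WT replicates 1 and 2 with Mll3-null replicate 3 against the rest (0.0033). In any case, 10 splits are too few for a share under 0.05.

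The same holds for the counts. Of the 10 splits, 4 gave at least as many genes at an unadjusted p under 0.05 as the real one, itself included (1093; highest other 1985, for WT replicates 1 and 2 with Mll3-null replicate 1 against the rest, a structure of the samples other than genotype), and 1 gave as many called lists, the real one (11; highest other 10). The other splits called from 2 to 10 lists each, so camera with a preset correlation also called lists under groupings other than genotype.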
